A study of Mus musculus with 6 samples.

How the data were processed

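RNA was sequenced from mouse embryonic fibroblasts of 2 genotypes, 3 libraries each, named WT and Fbxw7 knockout by the labels. Per the labels' protocols, cells grew in DMEM with 15% FBS and 1% NEAA, RNA was taken with Trizol and a column kit, and libraries were made with the Illumina TruSeq protocol; whether the kit or the counting used strand was not given in the sources used here. Per the submitters' processing notes, reads were handled with TopHat2 2.1.1, SAMtools 1.5, deepTools and Cufflinks 2.2.1 on the mouse build mm10; the annotation and its version were not given in the sources used here.

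The authors deposited a table of estimated counts, that is expected fragments per locus, with a status for each library, and a table of FPKM (fragments scaled to transcript length and library total), both with the column layout of Cufflinks tracking tables per the file headers. In the deposited estimated counts of each library, 88.9% to 89.4% of the values up to 1000 fragments were whole multiples of 1 step (tolerance 0.05), so each library had been multiplied by 1 factor; totals were 55720129 to 64198455 fragments after and 51152387 to 70625741 before that scaling. Reads shared between copies of a gene were divided by an estimate, which makes values of pseudogenes and near-identical families uncertain.

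The tables held 53323 loci, of which 1317 without a gene name (at most 3.13e-05% of a library) were left out, and 1256 carried several gene names, 545 of them several coding genes or no single gene. The status HIDATA marked 12 loci, 9 with a name, where estimation was skipped in at least 1 library because of too many fragments and the value was 0; these were left out of the tests. The 55 loci marked FAIL were kept. Positions and gene types came from GENCODE M21 on the same build, matched by symbol and position for 50421 of 52006 named loci.

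The design had assumed whole counts; as the values were expected counts, they were rounded to whole numbers and tested with edgeR 4.0.16 in R 4.3.3 (filterByExpr, TMM factors, robust quasi-likelihood fit, genotype as the only term, two-sided F test). Adjusted p-values are Benjamini-Hochberg values over all genes tested with a threshold of 0.05. Levels are CPM (counts scaled to a common library total with TMM factors), given as mean ± SD over 3 libraries; the error of a log2 fold change is its standard error, taken as the fold change divided by the square root of F. A 95% interval was computed from it for Fbxw7. At this depth all genes with a fold change in the text had at least 9 estimated fragments in the lower group unless CPM alone is given; PCR duplicates were not marked by molecular identifiers, so counting precision is an upper bound.

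The comparison, the gene lists and the naming rule were set before the data were examined. The 46 lists held 34 pathway lists, 11 cell marker lists and 1 list of sex-linked transcripts; of their entries 803 were tested, 111 fell below the count filter, 29 lay in a locus shared with another gene, 11 had no locus of that name and 2 were marked HIDATA. For each list the members past the threshold were counted, over all genes and adjusted over the list alone, and lists of at least 3 tested members were compared with all other genes by camera (limma 3.58.1, preset correlation 0.01, Benjamini-Hochberg over 43 lists), with an estimated correlation and with fry as alternatives. The text names Fbxw7; the 10 largest increases and 10 largest decreases among genes past the threshold with at least 10 CPM in the higher group, groups that did not overlap and no predicted or mitochondrial name; the 5 smallest adjusted p per direction among the rest; and from each list up to 4 members with the smallest adjusted p, or the 2 most abundant where none passed. Any FBXW7 substrate could be given as a value, and genes named outside this rule are said to be chosen after their values were seen. For 1 list a gene that the rule would name is not reported here.

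Alternatives were DESeq2 size factors, upper-quartile factors and library size only; no count filter, and a CPM of at least 1 in 3 libraries; the Wald test of DESeq2 1.42.0; the replicate number as a block; each library left out in turn; and limma on log2(FPKM + 1) or log2(FPKM + 0.1) at a mean FPKM of at least 1, or without that filter. Added after the data were seen were counts divided by each library's step, FAIL loci left out, chromosomes X and Y left out, replicates 1 and 2 of a genotype summed, and replicate 3 of both genotypes left out. Library pairs were compared by the median chi-square of their unscaled fragments over genes with at least 50 fragments, relative to sampling noise. The test was tried on simulated data: with 3 against 3 libraries and 16787 genes it recovered 23.9% of genes changed 1.5-fold, 68.7% of those changed 2-fold and 93.9% of those changed 4-fold, with 12 false calls, and camera called 2 lists beside the 1 that had been shifted. Tables and figures were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9. The rule for reading the limb genes was changed, and then changed again, after their values were seen. At first a decrease by unadjusted fry p, or a 95% interval of the mean below 0.5, counted against a larger share of limb cells, and the values met it. The p was then adjusted over 44 lists, and last a decrease together with an interval below 0 was asked for, which the values did not meet, so that explanation went from argued against to open. Variances and dispersions deposited beside the estimated counts were not used here.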

Results

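Total RNA of mouse embryonic fibroblasts (primary connective-tissue cells grown out of embryos) was sequenced in 6 libraries, 3 from wild-type (WT) cells and 3 from cells with a knockout of Fbxw7. Fbxw7 encodes the substrate-recognition part of an SCF ubiquitin ligase, which marks MYC, cyclin E, JUN, NOTCH and other proteins for degradation. The deposited table held estimated fragments per locus, which summed to 62551369, 64198455 and 64065298 for WT replicates 1, 2 and 3. Knockout replicates 1, 2 and 3 summed to 59154352, 60402238 and 55720129. Before the scaling applied by the authors, the same libraries held 66070336, 51152387, 57960343, 57728123, 60332878 and 70625741 fragments. Nothing in the labels said that the libraries of a genotype came from separate cultures or embryos, so p-values measured only the spread between these samples, which may be technical.

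Transcripts of Fbxw7 (chromosome 3, 84815268 to 84979198, plus strand, protein coding, mm10) were present in all 6 libraries. WT cells held 29.3 ± 0.869 CPM (counts scaled to a common library total; SD, n = 3) and the knockout-labelled cells 26.4 ± 1.97 (SD, n = 3), which was 89.8% of WT. The single libraries read 29.5, 28.4 and 30.1 CPM in WT and 27.6, 27.4 and 24.1 CPM in the knockout. The log2 fold change of -0.16 ± 0.10 (SE; 95% interval -0.39 to 0.07) did not pass the test (edgeR quasi-likelihood, Benjamini-Hochberg adjusted p = 0.332), although all 3 knockout libraries lay below all 3 WT libraries. This value sums reads over the whole gene, and the labels did not say which exons were deleted, so it does not check the genotype labels, and the libraries are called knockout as labelled.

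**Figure D1:**
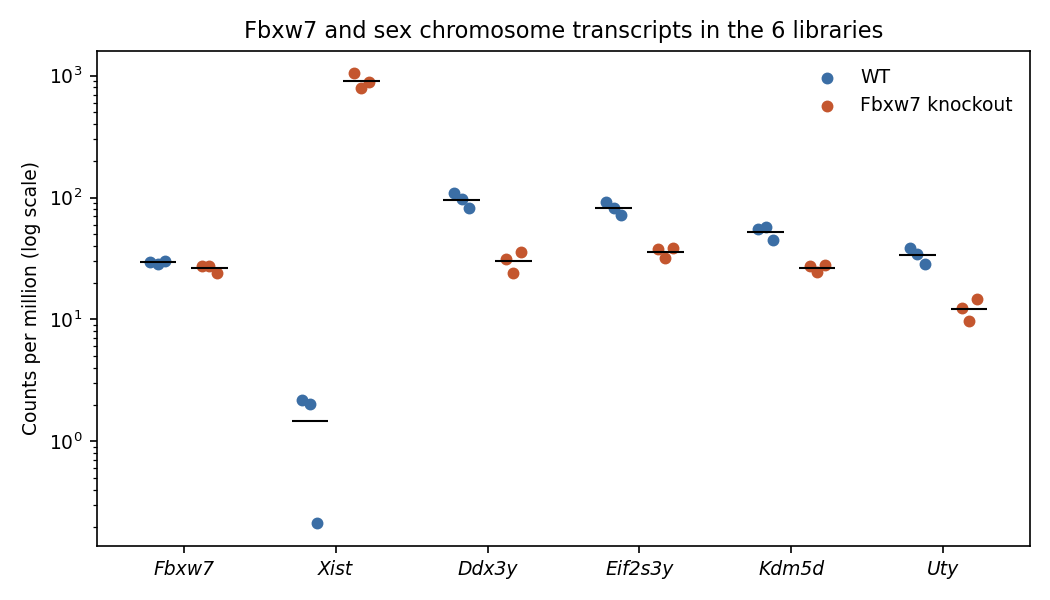
CPM on a log axis for Fbxw7, Xist and 4 Y-linked genes, with a point for each of the 3 WT and 3 knockout libraries and a line at each group mean. Fbxw7 lay at 24.1 CPM or above in every library, while Xist averaged 1.47 CPM in WT and 911 CPM in the knockout.

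The series compared the genotypes to find expression related to Fbxw7. Single genes moved from near absence to moderate expression in the knockout-labelled cells. Transcripts of Hoxd10 and Hoxd11 (1 shared locus on chromosome 2), which pattern limbs and the trunk, rose from 0.0609 ± 0.0103 to 24.0 ± 0.442 CPM (SD, n = 3 each). Pianp (chromosome 6, 124996694 to 125003096), a membrane protein gene, rose from 0.133 ± 0.0607 to 48.9 ± 2.58 CPM. Ptgis (chromosome 2, 167191805 to 167240604), the prostacyclin synthase gene, rose from 0.611 ± 0.363 to 50.8 ± 4.89 CPM. Tfpi, an inhibitor of blood coagulation (chromosome 2, 84432855 to 84476775), rose from 9.34 ± 1.75 to 145 ± 7.44 CPM, and the neutrophil chemokine gene Cxcl1 (chromosome 5, 90891241 to 90893115) from 10.7 ± 0.203 to 120 ± 16.6 CPM. On the log2 scale the increases were 8.58 ± 0.18 (SE) for Hoxd10/Hoxd11, 8.50 ± 0.25 for Pianp, 6.37 ± 0.35 for Ptgis, 3.95 ± 0.16 for Tfpi and 3.49 ± 0.13 for Cxcl1, with edgeR Benjamini-Hochberg adjusted p of 1.28e-06, 5.17e-06, 8.2e-05, 1.4e-05 and 9.34e-06. The cell adhesion gene Chl1 (log2 fold change 5.84 ± 0.53), the complement regulator Cd59a (5.11 ± 0.28), the actin regulator Wasf3 (4.97 ± 0.20) and the transcription factor gene Sp9 (6.24 ± 0.74) rose as well. Hoxa9, Hoxa10 and Hoxa11 were also among the largest or best supported increases, as was Xist, at 9.28 ± 0.71. Errors of genes near absence in WT, such as Hoxd10/Hoxd11 and Pianp, are understated, as counting error alone is larger there. Further names are uncertain: the processed pseudogene Rps13-ps1 (7.52 ± 0.24) can take reads of its near-identical parent gene, and Hoxa11os (6.42 ± 0.29) overlaps Hoxa11 on the opposite strand, while strand use in the counting was not given in the sources used here.

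Among the genes that fell, Cck, which encodes the peptide hormone cholecystokinin (chromosome 9, 121489824 to 121495694), went from 453 ± 225 to 14.5 ± 1.73 CPM (SD, n = 3 each). Lgr5, a receptor of the Wnt-enhancing R-spondins (chromosome 10, 115450311 to 115587780), went from 230 ± 43.3 to 14.6 ± 4.49 CPM. Oas3, an interferon-induced antiviral enzyme (chromosome 5, 120753098 to 120777661), fell from 49.8 ± 8.94 to 1.81 ± 0.421 CPM, Prex2, a Rac exchange factor (chromosome 1, 10993465 to 11303681), from 44.8 ± 5.19 to 1.71 ± 0.23 CPM, and Prdm16, a transcriptional regulator known from brown fat (chromosome 4, 154316125 to 154636873), from 11.6 ± 1.05 to 0.363 ± 0.216 CPM. Their log2 fold changes were -4.97 ± 0.36 for Cck, -3.98 ± 0.27 for Lgr5, -4.78 ± 0.22 for Oas3, -4.71 ± 0.16 for Prex2 and -4.99 ± 0.41 for Prdm16, with edgeR Benjamini-Hochberg adjusted p of 0.000275, 0.000203, 3.23e-05, 7.27e-06 and 0.000491. The progesterone receptor gene Pgr (-6.51 ± 0.33), the neurotrophin gene Ntf3 (-5.07 ± 0.31), the secretory granule gene Scg2 (-5.06 ± 0.67), Frmd4b (-4.61 ± 0.29), Sema5b (-4.40 ± 0.26), Crybg1 (-4.10 ± 0.23) and B3gnt3 (-4.03 ± 0.63) also fell. Smaller and tight decreases were those of the metalloprotease gene Mmp23, from 65.3 ± 2.94 to 16.5 ± 2.15 CPM, and of the shared locus of Hoxc10 and Hoxc5, from 107 ± 0.824 to 40.1 ± 2.45 CPM. Rpl39l (-6.37 ± 0.26) is uncertain because it is a near copy of Rpl39 and can share its reads.

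**Figure D2:**
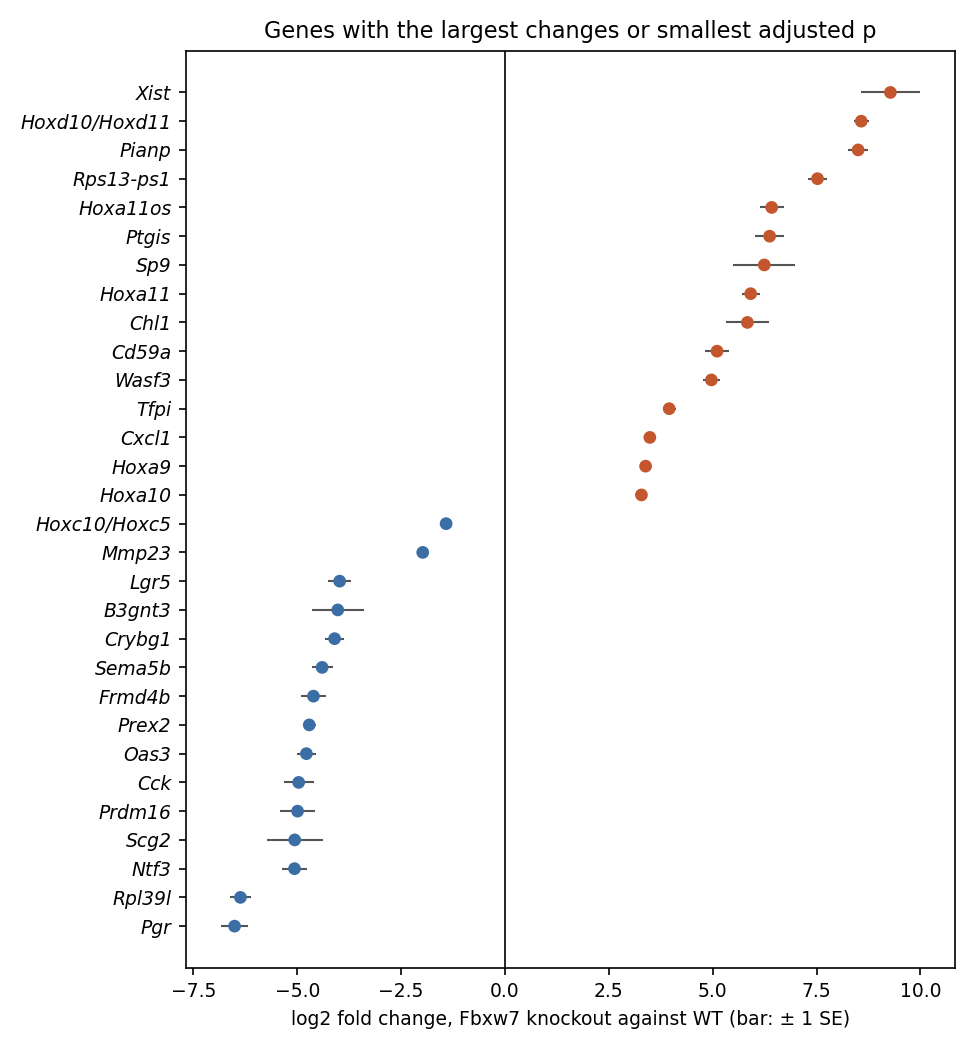
Log2 fold change of the knockout against WT for the genes with the largest increases and decreases and those with the smallest adjusted p; points are edgeR estimates and bars 1 SE. Changes ran from 9.28 for Xist to -6.51 for Pgr. Bars can understate the error of genes near absence in 1 group.

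In all, 2705 of 16787 tested genes (16.1%) passed an adjusted p of 0.05 in edgeR, 1348 higher and 1357 lower in the knockout, and 692 of the higher and 605 of the lower genes changed at least 2-fold. The groups did not overlap for 6321 genes (37.7%, where chance gives 10% for 3 against 3), and 5299 genes had an unadjusted p under 0.05. Of the genes called, 49.8% were higher; scaling by library size only gave 65.7%, and it moved the median log2 fold change of all genes from 0.007 to 0.105. The count was 1302 without WT replicate 1, 1271 without WT replicate 2, 1169 without knockout replicate 1 and 1462 without knockout replicate 2. It was 6993 without replicate 3 of both genotypes and 484 with replicates 1 and 2 of each genotype summed to 1 sample, both chosen after the data were seen. Replicates 1 and 2 differed by 6.44 (WT) and 5.8 (knockout) times the sampling noise, and by 21.9 to 35.3 times from the third library of their genotype.

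Transcripts that mark sex moved with the genotype labels. Xist, the noncoding RNA that silences an X chromosome in XX cells (chromosome X, 103460366 to 103483254), was at 1.47 ± 1.09 CPM in WT and 911 ± 126 CPM in the knockout (SD, n = 3 each; adjusted p = 0.00033 in edgeR). The Y-linked genes were detected in both genotypes and fell: Ddx3y from 95.9 ± 13.8 to 30.4 ± 6.01 CPM, Eif2s3y from 81.9 ± 10.1 to 36.0 ± 3.57 CPM, Kdm5d from 52.3 ± 6.46 to 26.6 ± 2.0 CPM and Uty, which was chosen after its values were seen, from 33.8 ± 5.13 to 12.3 ± 2.48 CPM. They stood at 31.7%, 44.0%, 50.9% and 36.3% of their WT means. The sex transcripts thus differed in the same libraries as every gene group described here, and the labels gave no sex or embryo. With chromosomes X and Y left out, a choice made after the data were seen, 2610 genes passed, 2592 of them shared with the 2705.

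Genes of the Hox clusters, transcription factors that give cells their position along the body and limb axes, split by cluster. In the A cluster 6 of 10 tested loci rose, in the D cluster 3 of 6 rose, in the B cluster 5 of 9 fell and in the C cluster 4 of 6 fell. Hoxa9 (chromosome 6, 52223100 to 52231089) rose from 5.57 ± 0.744 to 58.2 ± 1.01 CPM, Hoxa10 (52231197 to 52240854) from 7.93 ± 0.343 to 77.3 ± 3.29 CPM and Hoxa11 (52242106 to 52245810) from 0.813 ± 0.125 to 49.2 ± 10.5 CPM (SD, n = 3 each). Their log2 fold changes were 3.39 ± 0.13 (SE), 3.29 ± 0.10 and 5.92 ± 0.22, with edgeR adjusted p of 9.78e-06, 5.16e-06 and 9.78e-06. Hoxd13 (chromosome 2) was at 0.0163 CPM in WT and 1.20 CPM in the knockout, so no fold is given. The remaining changed loci were chosen after their values were seen. Hoxa7 (0.77 ± 0.14), the shared locus Hoxa2/Hoxa3 (0.89 ± 0.18) and Hoxd9 (0.81 ± 0.16) rose, and Hoxa13 rose from 0.0332 to 1.38 ± 1.81 CPM, of which knockout replicate 3 alone held 3.46 CPM. Hoxb3 (-0.79 ± 0.11), Hoxb4 (-0.65 ± 0.10), Hoxb5 (-0.83 ± 0.16), Hoxb6 (-0.72 ± 0.10), Hoxc6 (-0.72 ± 0.10), Hoxc8 (-0.73 ± 0.14) and Hoxc9 (-1.39 ± 0.17) fell, and Hoxb13 fell from 0.31 to 0.0172 CPM. Overlapping and antisense transcripts within the clusters make the split of reads between neighbours uncertain. Of the fixed list of Hox and other positional genes, 8 of 25 tested members rose and 6 fell (8 and 8 adjusted over the list alone); camera gave an adjusted p of 0.000266, and adjusted p = 0.568 with an estimated correlation. Without WT replicate 1 or WT replicate 2, 5 members rose.

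**Figure D3:**
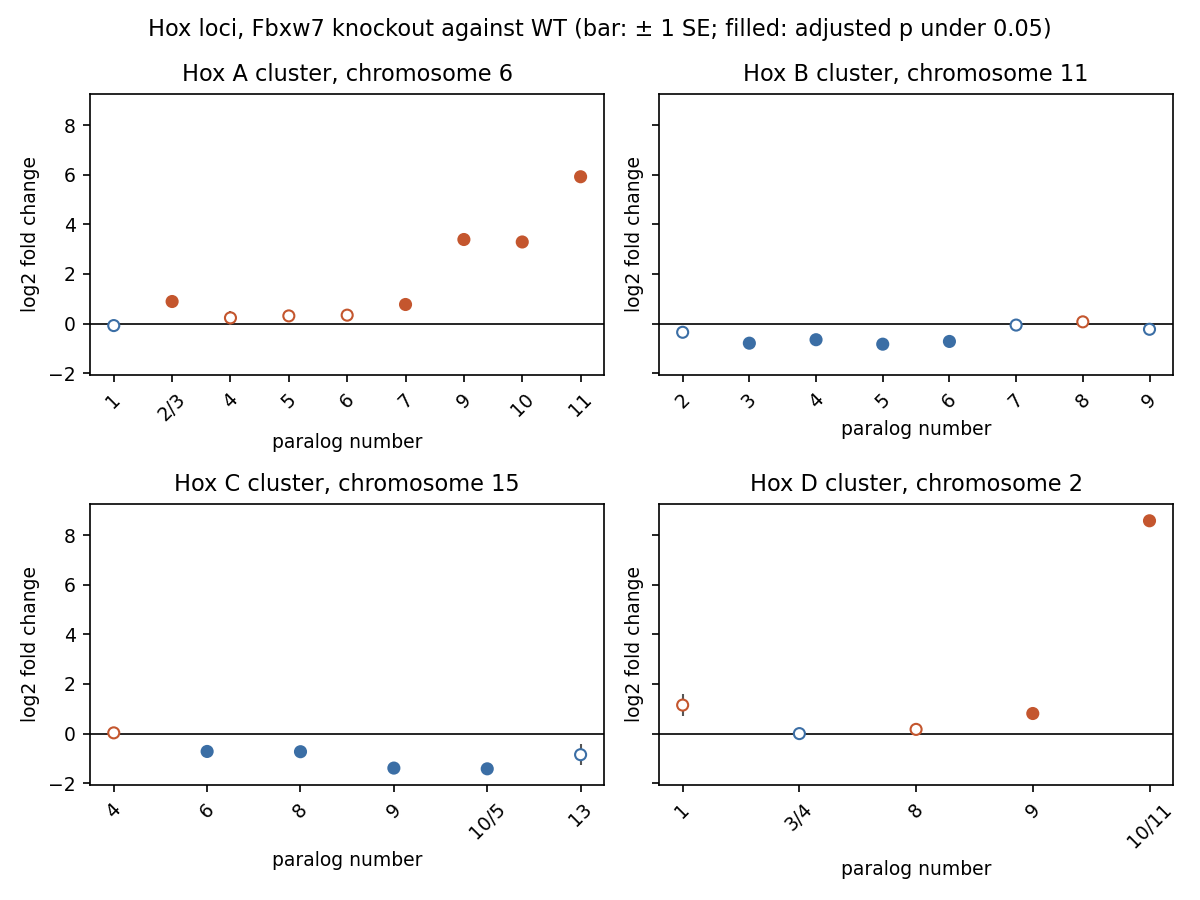
Log2 fold change of the knockout against WT (edgeR, bar 1 SE) for each tested Hox locus, ordered by paralog number within the A, B, C and D clusters; filled points passed an adjusted p of 0.05. Loci with a group mean under 0.05 CPM (Hoxa13, Hoxb13 and Hoxd13) are left out because they give no fold. Hoxa9 to Hoxa11 and Hoxd10/Hoxd11 stood highest, while changed B and C cluster loci lay below 0. The bar of Hoxd10/Hoxd11 understates its error.

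Genes of glycolysis and the hypoxia response rose: 17 of 24 tested members were higher and 1 lower (21 and 2 adjusted over the list alone), with a median log2 fold change of 0.75. Ndrg1, a hypoxia-induced gene, rose from 29.4 ± 4.54 to 157 ± 17.3 CPM (SD, n = 3 each; log2 fold change 2.42 ± 0.15 SE). Pdk1, which holds pyruvate back from mitochondria (1.35 ± 0.10), Egln3, an oxygen-sensing hydroxylase gene (2.82 ± 0.25), and Bnip3, a mitophagy receptor gene (1.73 ± 0.16), rose as well. The hexokinase gene Hk1, chosen after its value was seen as the only member that fell, changed by -0.60 ± 0.08. Gapdh, chosen after its values were seen, read low for a gene that every cell uses, at 3.97 CPM in WT and 6.82 CPM in the knockout. It has many near-identical pseudogenes that can share its reads, so its level is uncertain. Eno1, also counted among the 17, read 20.5 CPM in WT and 30.9 CPM in the knockout. Shared reads can make the level of Eno1 and of other members uncertain too. Camera gave an adjusted p of 2.69e-12 against all other genes, and adjusted p = 0.152 with an estimated correlation. The number that rose was 8 without WT replicate 1, 9 without WT replicate 2 and 10 without knockout replicate 1.

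Targets of ATF4, the transcription factor of the integrated stress response that induces amino acid synthesis and transport, rose in 16 of 23 tested members (17 higher and 1 lower adjusted over the list alone; median log2 fold change 0.69). Cth, an enzyme of cysteine synthesis, rose from 6.94 ± 0.802 to 42.0 ± 6.31 CPM (SD, n = 3 each; 2.60 ± 0.15 on the log2 scale). The proline synthesis gene Aldh18a1 (0.76 ± 0.09), the lipoprotein receptor gene Vldlr (from 30.2 ± 4.5 to 74.3 ± 12.5 CPM) and the amino acid transporter subunit gene Slc3a2 (0.71 ± 0.09) rose, and Slc7a11, the cystine transporter gene, rose by 1.44 ± 0.18. Camera gave an adjusted p of 1.99e-11, and adjusted p = 0.0741 with an estimated correlation. Of the circadian clock list, 10 of 18 tested members rose (13 adjusted over the list alone; median 0.50), among them the repressors Nfil3 (1.24 ± 0.12) and Bhlhe40 (1.29 ± 0.15), the core activator Arntl (0.55 ± 0.08) and Per2 (1.09 ± 0.21). Its camera adjusted p was 0.00026, and adjusted p = 0.568 with an estimated correlation. The clock members that rose numbered 4 without WT replicate 1, 4 without WT replicate 2 and 3 without knockout replicate 1.

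Some inflammatory and matrix-degrading genes rose, although of the 20 tested members of the matrix protease list 4 rose and 4 fell (camera adjusted p = 0.772). The stromelysin gene Mmp3 rose from 27.3 ± 4.15 to 225 ± 18.2 CPM, the collagenase gene Mmp13 from 0.791 ± 0.169 to 20.5 ± 9.57 CPM, the cytokine gene Il6 from 0.382 ± 0.0716 to 9.16 ± 4.25 CPM and the chemokine gene Cxcl5 from 13.7 ± 6.66 to 200.2 ± 30.7 CPM (SD, n = 3 each). Lcn2, an iron-binding acute-phase gene, rose by 1.80 ± 0.24 on the log2 scale. Of the NF-kB target and cytokine list, 7 of 25 rose and 2 fell (9 and 2 adjusted over the list alone); those that fell were the chemokine genes Ccl5 (-1.10 ± 0.17) and Ccl20 (-2.26 ± 0.39), chosen after their values were seen. The camera adjusted p was 5.73e-05, and adjusted p = 0.568 with an estimated correlation, and 11 members rose without WT replicate 3. Of the list of cyclin-dependent kinase inhibitors and factors secreted by senescent cells, 6 of 20 rose and 2 fell (7 and 4 adjusted over the list alone). Those that rose most were secreted proteases and cytokines shared with the lists above. The 6 also held a kinase inhibitor gene, so the inhibitors did not all fall. Those that fell, chosen after their values were seen, were Cdkn2a (-0.55 ± 0.13), which encodes cell cycle inhibitors, and Igfbp7 (-0.97 ± 0.17). The list's median was 0.08 and its mean 0.89, with a camera adjusted p of 8.26e-05, and adjusted p = 0.152 with an estimated correlation. Only 1 member fell without WT replicate 1, WT replicate 2, knockout replicate 1 or knockout replicate 2.

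Immediate early genes of the AP-1 list, which respond within minutes to growth factors and handling, rose in 5 of 20 tested members and fell in 1 (8 and 1 adjusted over the list alone). Fos rose from 3.54 ± 1.09 to 12.2 ± 3.57 CPM, Egr1 from 44.4 ± 20.8 to 146 ± 36.5 CPM, Ier2 from 28.5 ± 6.93 to 74.7 ± 20.9 CPM, Ier3 from 33.7 ± 4.74 to 73.3 ± 13.8 CPM and Junb from 47.9 ± 15.2 to 137 ± 52.6 CPM (SD, n = 3 each). The phosphatase gene Dusp1 (-0.75 ± 0.20), chosen after its value was seen, fell. The camera adjusted p was 0.0327, and adjusted p = 0.873 with an estimated correlation. It was 0.122 without WT replicate 1, 0.0725 without WT replicate 2 and 0.0807 without knockout replicate 2. The number that rose was 3 without WT replicate 2, 8 without WT replicate 3 and 3 without knockout replicate 2, and none fell without WT replicate 2, WT replicate 3, knockout replicate 1, knockout replicate 2 or knockout replicate 3 (0 members in edgeR).

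Contractile genes fell in 8 of 19 tested members (9 adjusted over the list alone; median log2 fold change -0.66). Myh10, a nonmuscle myosin heavy chain gene, fell from 978 ± 94.0 to 482 ± 6.66 CPM, the calponin gene Cnn2 from 751 ± 171 to 321 ± 48.5 CPM and the adhesion gene Vcl from 638 ± 131 to 351 ± 43.7 CPM (SD, n = 3 each), and Smtn changed by -0.60 ± 0.10. The camera adjusted p was 5.7e-05, and adjusted p = 0.773 with an estimated correlation. Only 3 members fell without knockout replicate 1 and 3 without knockout replicate 2.

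Some lipid synthesis genes fell. Fasn, the fatty acid synthase gene, went from 623 ± 85.5 to 285 ± 21.8 CPM and Acly, which supplies cytosolic acetyl-CoA, from 609 ± 116 to 297 ± 36.5 CPM (SD, n = 3 each). The fatty acid list fell in 5 of 17 members (8 adjusted over the list alone; median -0.39), the others being Aacs (-0.49 ± 0.09), Lpin1 (-0.76 ± 0.15) and Acss2 (-1.22 ± 0.33, chosen after its value was seen). Of the cholesterol synthesis list, 20 of 21 tested members had a log2 fold change below 0 and 2 passed, Lss (-1.02 ± 0.20) and Mvk (-0.86 ± 0.19), with 10 adjusted over the list alone and a median of -0.54. Camera gave adjusted p of 0.00255 for fatty acid and 0.000385 for cholesterol genes, and adjusted p = 0.773 and adjusted p = 0.873 with an estimated correlation. By fry neither list was called (adjusted p = 0.11 and adjusted p = 0.222). The fatty acid count was 3 without WT replicate 1, WT replicate 2 or knockout replicate 1 and 9 without WT replicate 3. The cholesterol count was 0 without WT replicate 1, WT replicate 2 or knockout replicate 2, 1 without knockout replicate 1, 8 without WT replicate 3 and 16 without knockout replicate 3. In DESeq2 with all libraries it was 11 (12 at unadjusted p under 0.05 in edgeR).

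Notch pathway genes, read here because NOTCH proteins are FBXW7 substrates, fell in 4 of 10 tested members and rose in 1 (the same numbers adjusted over the list alone; median -0.62). The ligand genes Jag1 (from 50.5 ± 1.78 to 32.8 ± 1.46 CPM) and Dll1 (from 5.46 ± 1.34 to 2.71 ± 0.13 CPM) and the target genes Hes1 (from 82.5 ± 1.46 to 53.5 ± 8.47 CPM) and Hey2 (from 1.61 ± 0.852 to 0.034 ± 0.0452 CPM) fell (SD, n = 3 each). Dtx4 (0.70 ± 0.15), chosen after its value was seen, rose. The camera adjusted p was 0.0393, and adjusted p = 0.568 with an estimated correlation. It was 0.05 without WT replicate 2, 0.188 without knockout replicate 3, 0.17 with the CPM filter and 0.0502 with the replicate block, so the call was lost in each of these. Without WT replicate 1, WT replicate 2 or knockout replicate 1, 2 members fell, and none rose without these or knockout replicate 2 (0 in edgeR).

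Interferon response genes fell in 7 and rose in 2 of 29 tested members (12 and 4 adjusted over the list alone; median -0.20). Beside Oas3, Oas2 fell from 48.1 ± 3.96 to 21.9 ± 6.23 CPM and the RNA sensor gene Ifih1 from 78.7 ± 8.81 to 54.4 ± 3.82 CPM, while the chemokine gene Cxcl10 rose from 33.7 ± 3.65 to 148 ± 73.5 CPM (SD, n = 3 each) and Mx2, chosen after its value was seen, by 0.44 ± 0.10 on the log2 scale. The camera adjusted p was 0.0413, and adjusted p = 0.873 with an estimated correlation. It was 0.131 without WT replicate 1 and 0.587 without knockout replicate 3. The number that fell was 2 without WT replicate 1, 2 without WT replicate 2, 3 without knockout replicate 1 and 3 without knockout replicate 2. The number that rose was 1 without WT replicate 1, knockout replicate 1 or knockout replicate 2, 0 without WT replicate 2 and 4 without knockout replicate 3 or with library size only. Of the heat shock list, 4 of 17 fell (5 lower and 1 higher adjusted over the list alone; median -0.23): the chaperone genes Cryab (-0.93 ± 0.11), Hspa1b (-1.08 ± 0.19) and Hsph1 (-1.09 ± 0.20) and the co-chaperone gene Bag3 (-0.54 ± 0.11). Hspa1b is nearly identical to Hspa1a, so its value is uncertain. The camera adjusted p was 0.0273, and adjusted p = 0.773 with an estimated correlation. It was 0.139 without WT replicate 3, and 7 members fell without knockout replicate 3.

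Transcripts of proteins that FBXW7 marks for degradation formed no called list. Of 27 tested, 4 rose and 1 fell (6 and 4 adjusted over the list alone), with a median log2 fold change of -0.08, a mean of 0.03 and a camera adjusted p of 0.996; with library size scaling the median was 0.01. Cebpa, a transcription factor gene of fat and myeloid cells (1.76 ± 0.25), Junb (1.52 ± 0.33) and the glycolytic enzyme gene Eno1 (0.59 ± 0.15) rose. Shared reads can make the Eno1 value uncertain. Cebpd (0.80 ± 0.22, chosen after its value was seen) rose as well, and Klf5 (-1.42 ± 0.16) fell. Myc was at 42.1 ± 22.7 CPM in WT and 86.8 ± 9.69 CPM in the knockout (SD, n = 3 each), a log2 difference of 1.04 ± 0.33 that did not pass (edgeR adjusted p = 0.0669). Ccne1 (-0.22 ± 0.19), Jun (0.07 ± 0.27), Notch1 (-0.25 ± 0.35), Mcl1 (-0.26 ± 0.09) and Srebf1 (-0.45 ± 0.13) did not pass either. Messenger RNA levels do not show protein stability, which was not measured here. The number that rose was 1 without WT replicate 1, WT replicate 2, knockout replicate 1 or knockout replicate 2, and 3 fell without WT replicate 3. In DESeq2 5 rose and 4 fell, without replicate 3 of both genotypes 10 rose and 6 fell, and with replicates 1 and 2 summed 0 rose in edgeR and 1 fell.

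Few members of the growth-related lists passed with all 6 libraries. Ribosomal protein genes rose in 3 of 28 members (2 adjusted over the list alone; median 0.26), Rpl10a (0.77 ± 0.15), Rps24 (0.52 ± 0.10) and Rps19 (0.39 ± 0.10), although pseudogenes share reads with this family and make its values uncertain. Genes of the G1/S transition rose in 1 of 28 members, E2f2 (1.54 ± 0.31), with 1 adjusted over the list alone and a median of 0.38. Camera gave adjusted p of 0.0146 and 0.0429 for these lists, and adjusted p = 0.873 for both with an estimated correlation; for ribosomal genes it was 0.106 without WT replicate 2, and for G1/S genes 0.235 without WT replicate 1, 0.318 without WT replicate 2, 0.0722 without knockout replicate 2 and 0.145 without knockout replicate 3. The G1/S count was 19 without WT replicate 3 and 0 in edgeR without WT replicate 1, WT replicate 2, knockout replicate 1 or knockout replicate 2, and the ribosomal count was 0 in edgeR without knockout replicate 1. It was 5 with upper-quartile factors, 7 with library size only and 7 in DESeq2. Of the MYC targets, 2 of 30 rose, Ldha (0.70 ± 0.17) and Odc1 (1.00 ± 0.16), and Cdk4 (-0.39 ± 0.11) fell (1 higher adjusted over the list alone). The MYC list did not pass (camera adjusted p = 0.0535) but did without WT replicate 3 (1.02e-05, with 16 members higher), without knockout replicate 2 (0.0402) and with the replicate block (0.0157). Without any other single library 1 MYC target rose, and without each of the 6 libraries none fell (0 in edgeR). Genes of the G2/M phase passed in 0 of 30 members in edgeR, 0 at unadjusted p under 0.05 and 0 in DESeq2. Without knockout replicate 3, 2 were lower, and without replicate 3 of both genotypes 10 were higher and 5 lower. Top2a was at 111 ± 42.0 and 135 ± 29.6 CPM and Tpx2 at 75.5 ± 34.7 and 77.7 ± 28.7 CPM in WT and knockout.

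**Figure D4:**
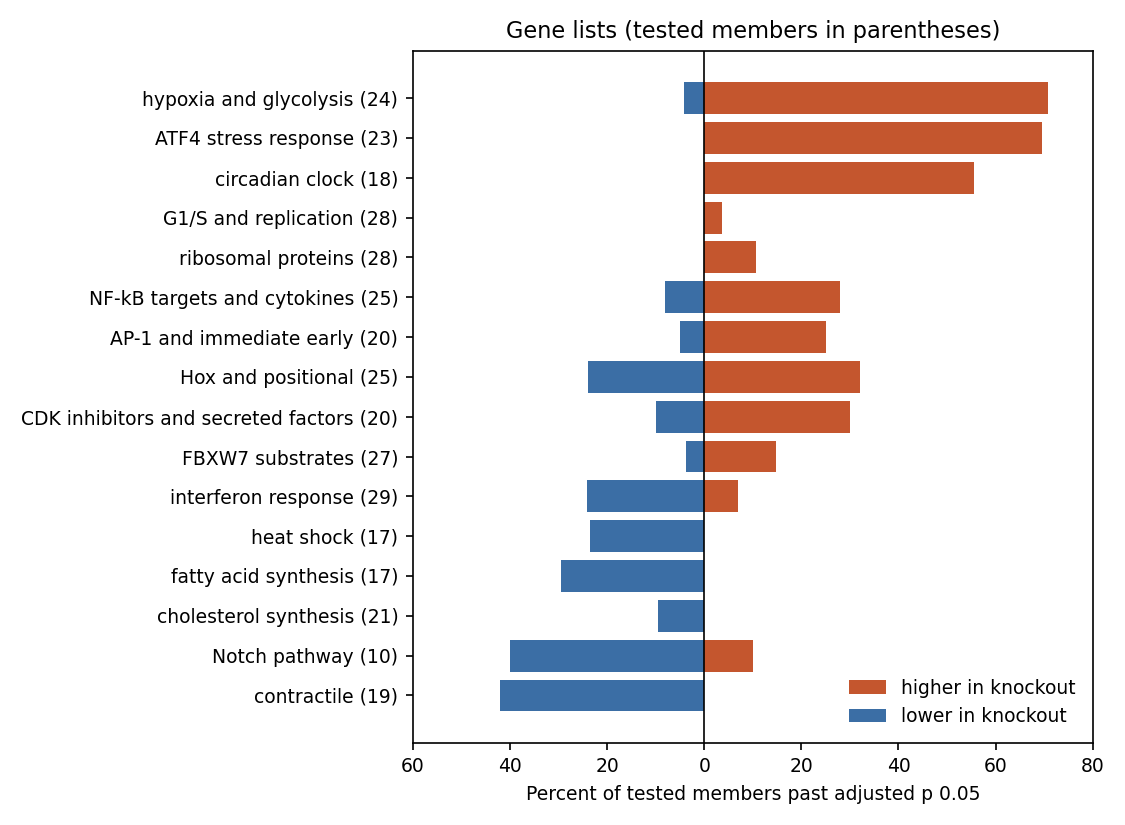
Share of tested members of each list that passed an adjusted p of 0.05 in edgeR, with members higher in the knockout to the right and lower to the left, for the 15 lists called by camera with a preset correlation and the FBXW7 substrates. Of hypoxia and glycolysis genes 17 of 24 were higher and of contractile genes 8 of 19 lower.

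The number of members that passed depended on how replicates 1 and 2 were treated. With these summed to 1 sample per genotype, the members that rose were 5 for hypoxia and glycolysis, 4 for ATF4 targets, 2 for the clock list, 4 each for the Hox, NF-kB and senescence lists and 1 for the AP-1 list. Those that fell were 1 each for the contractile, fatty acid, interferon, heat shock and Hox lists, and no member of the cholesterol, Notch, ribosomal, G1/S or MYC lists passed (0 in edgeR). Without replicate 3 of both genotypes more passed: 21 hypoxia and glycolysis genes, 20 ATF4 targets, 18 NF-kB, 11 AP-1, 11 senescence, 13 ribosomal, 22 G1/S genes and 23 MYC targets rose, and 20 cholesterol, 13 fatty acid, 14 contractile, 13 interferon and 8 heat shock genes fell. Against these directions, 7 interferon, 4 heat shock, 3 contractile and 1 fatty acid genes rose without replicate 3 of both genotypes. There 5 senescence, 3 NF-kB, 2 AP-1 and 2 hypoxia and glycolysis genes, 1 ATF4 target and 1 MYC target fell. Both alternatives were chosen after the data were seen.

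Of 43 lists tested, camera with its preset correlation called 15, 9 higher and 6 lower. Splits of the 6 libraries that mixed the genotypes gave 8 to 16 lists by the same test. A call by this test alone therefore does not set the genotypes apart. With an estimated correlation camera called 0, with 3 lists at unadjusted p under 0.05. Fry, which asks whether a list's members move on balance 1 way, called 8. These were the hypoxia and glycolysis, ATF4, clock, Hox, NF-kB, senescence, Notch and Wnt lists. The contractile, AP-1, fatty acid, cholesterol, interferon, heat shock, ribosomal and G1/S lists were not called by fry. Markers of cell types that an embryo culture can hold did not form a called list in the main comparison. Some alternatives did call such lists: cartilage and bone with the CPM filter or without WT replicate 3, and smooth muscle with the replicate block. Of the fibroblast markers 2 of 11 rose and 2 fell (3 and 3 adjusted over the list alone; median 0.00, mean 0.50): Lum from 13.8 ± 8.88 to 233 ± 122 CPM, Dcn from 631 ± 307 to 1855 ± 186 CPM, Vim (-0.83 ± 0.15) and Prrx1 (-0.40 ± 0.11). Endothelial markers rose in 1 of 6 (Eng, from 4.64 ± 0.998 to 45.2 ± 2.15 CPM) and fell in 2 (Kdr, -2.99 ± 0.39, and Tek, -2.45 ± 0.55), the same numbers adjusted over the list alone. Their median was -0.20 and their mean -0.35 while camera's direction was up. Fibroblast markers that rose numbered 1 without WT replicate 2, knockout replicate 1 or knockout replicate 2, and those that fell 0 in edgeR without knockout replicate 1 and 1 without WT replicate 1, WT replicate 2, knockout replicate 2 or knockout replicate 3. Of the endothelial markers 1 fell without WT replicate 1, WT replicate 2, knockout replicate 1 or knockout replicate 2.

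The deposited FPKM table of the same libraries gave a second reading. Of 13176 genes with a mean FPKM of at least 1, limma on log2(FPKM + 1) called 1492 (568 higher, 38.1% of those called), and 1370 were shared with the 2705 genes from the counts, all 1370 in the same direction. Log2 fold changes from both tables correlated across genes at r = 0.921; genes are not independent replicates. Fbxw7 was at -0.23 on the log2(FPKM + 1) scale, which understates the change of low genes, and did not pass.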

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

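Tests in this part were chosen or reworded after the results were seen, except the comparison of genes near Fbxw7 with other autosomal genes.

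Of 9 named loci without an estimate in 1 or more libraries, which stood outside the comparison, 3 are given here because they were abundant and all knockout libraries with a value lay above WT. The locus Gm26917/Gm42418, unmeasured in WT replicate 2, had a ratio of knockout to WT mean CPM of 2.23 (352 CPM in WT and 787 CPM in the knockout). Postn, an extracellular matrix gene, unmeasured in knockout replicate 3, had a ratio of 1.56 (8310 CPM in WT and 13000 CPM in the knockout). Col12a1, a collagen gene unmeasured in the same library, had a ratio of 1.49 (8940 CPM in WT and 13300 CPM in the knockout). The others went both ways. Of those unmeasured in WT replicate 2, chosen after their values were seen, CT010467.1 was at 3880 CPM in WT and 7750 CPM in the knockout with overlapping libraries, Cmss1 had a ratio of 1.32 and Filip1l one of 0.712, while 4930562D21Rik, unmeasured in knockout replicate 3, had a ratio of 1.54 at under 1 CPM. No difference was tested for these loci.

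Xist was high and Y-linked transcripts were lower but present in the knockout-labelled libraries. An exchange of 1 WT and 1 knockout library is argued against, as over all tested genes 0 libraries correlated less with their own genotype than with the other (at least 0.982 within and at most 0.965 between genotypes). A mixture of XX and XY cells in the knockout cultures may account for part of the pattern. Each Y-linked gene stood at 25% to 53.8% of its WT mean in each knockout library. Of 9 tested genes that escape X inactivation 1 rose and all 9 had a log2 fold change above 0. The rule for a mixture asked that most of these 9 rise past the threshold, which was not met. A mixture alone would lower all Y-linked genes of a library alike. Yet in each knockout library Ddx3y stood lowest and Kdm5d highest, at 25% and 46.5% in knockout replicate 2. That mixture cannot be told apart from an effect of the genotype on these transcripts, because the sex-linked transcripts differ between the same libraries as the genotype labels and the labels give no sex. X-linked genes were 104 of the 2705 changed genes. With 597 tested, they could not have been most of these, whatever their dosage. Of the X-linked genes 17.4% changed against 16.0% of autosomal genes, an odds ratio of 1.1 (95% interval 0.881 to 1.37). These values do not test effects of sex on autosomal genes, which stay open.

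Hox genes of the A and D clusters with high paralog numbers were higher in the knockout-labelled libraries. In 0 of the 9 tested loci from paralog 7 on did 2 or more knockout libraries stay at or below the highest WT library. Most of the Hoxa13 level lay in knockout replicate 3. As 8 of the 9 loci had already been called higher, this count was close to fixed and cannot test for a single deviating library. A larger share of limb cells could carry such a Hox code, yet of 11 limb mesenchyme genes outside the clusters 3 fell (Hand2, Lhx9 and Msx2, chosen after their values were seen) and as a list they went down (fry adjusted p = 0.0443 over 44 lists). Among these 11 genes 0 passed higher. Alx4 read 61.2 ± 5.52 CPM in WT and 10.1 ± 15.8 CPM in the knockout (edgeR adjusted p = 0.192). A larger share of limb cells stays open all the same. The log2 fold changes had both signs (median -0.03, mean -0.56, 95% interval -1.31 to 0.20), although genes are not independent replicates. WT cells also already expressed some of these genes, such as Shox2 at 47.7 CPM. A different origin of the cells along the body axis and an effect of the genotype were not tested and stay open.

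Among the changed genes, 61 were at least 32-fold apart, 45 higher and 16 lower in the knockout, on 18 chromosomes. A strain segment kept around the targeted gene is argued against as the source of most of the 61. Of these, 1 lay within 10 Mb of Fbxw7 (upper 95% Clopper-Pearson limit 8.8%) and 2 lay on chromosome 3. Over all changed genes, 31 of 168 genes in that window changed, an odds ratio of 1.18 (0.772 to 1.76) against the other autosomal genes. With 168 tested, the window could not have held most of the changed genes. The odds ratio therefore shows only that no large local excess was seen, and a small one stays open. Strain variants in gene copies cannot be told apart from other sources here, because pseudogenes made up 8.2% of the 61 and 4.7% of the other changed genes, too few to decide (odds ratio 1.8, 0.553 to 4.57, Fisher's exact p = 0.215). Unlike backgrounds or embryos of the genotypes elsewhere in the genome stay open as well.

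The 6 libraries can be split into 3 and 3 in 10 ways, which cannot give a share under 0.05. The real split gave 2705 genes in edgeR and was the 1 split with that many. The highest other gave 0 genes past the threshold, while 68 to 1278 genes in the other splits had an unadjusted p under 0.05. Each other split mixes the genotypes within its groups, so any difference between the labelled sets widens the spread there. The 0 was therefore close to fixed and does not bear on the cause of the difference. For lists called by camera the real split gave 15 and the highest other 16, and 3 of the 10 splits gave at least as many as the real one.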

How the results depend on the processing

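The scalings, filters, tests, block, single libraries left out and FPKM readings were planned; step-divided counts, FAIL loci or chromosomes X and Y left out, summed replicates and the removal of replicate 3 were chosen after the data were seen. Every gene called both in an alternative and in the comparison of all 6 libraries had the same direction. RLE factors, upper-quartile factors and library size gave 2703, 2796 and 2994 genes, sharing 2655, 2560 and 2374 with the 2705. No filter gave 2638, the CPM filter 2353, DESeq2 3639 (2673 shared), step-divided counts 2701, FAIL loci left out 2693 and X and Y left out 2610.

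Leaving out single libraries gave 1169 to 3282 genes, 605 to 1615 higher, 564 to 1727 lower and 860 to 1430 at least 2-fold changed; fewer samples also mean fewer degrees of freedom. Without replicate 3 of both genotypes 6993 genes passed (3499 higher, 3494 lower, 1946 at least 2-fold); the cause was not tested. With replicates 1 and 2 summed, 484 passed (283 higher, 201 lower, 451 at least 2-fold), with 2 samples per group. The FPKM table gave 1492 with a pseudocount of 1 (568 higher, 447 at least 2-fold), 1558 with 0.1 (589 higher, 597 at least 2-fold) and 1285 without a filter (569 higher, 716 lower, 380 at least 2-fold); the cause was not tested.

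Lists called were 12 to 18 with a library left out (7 to 11 higher, 4 to 7 lower). With an estimated correlation camera called 0 lists, 0 higher and 0 lower, with 3 at unadjusted p under 0.05; fry called 8, of which 2 lower. Fbxw7 kept its direction and did not pass in any alternative, at -0.19 to -0.10 with single libraries left out. It was at -0.23, -0.27 and -0.23 in the FPKM readings (pseudocount 1, 0.1 and 1 without a filter). The value was -0.20 with summed replicates, -0.075 without replicate 3 and, nearest to no change, -0.06 with library size only.

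The replicate numbers did not pair the samples: same-numbered libraries deviated together at 0.02, 0.10 and 0.08. With the replicate number as a block 2356 genes and 18 lists passed, and 2065 genes were shared. Krt19 was at 0.39 under the block.

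Of 199 named genes past the threshold, all those tested in an alternative had the same direction in it; 131 to 184 passed without a single library, 142 and 148 of 172 tested in the filtered FPKM readings, 124 in the unfiltered one and 77 with summed replicates. Of the 30 genes named for size or adjusted p, 26 to 30 passed in each alternative.

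Among the named genes, directions turned only in those that had not passed with all libraries, and the cause was not tested. Lists that were not called could turn as well. Camera's direction for the FBXW7 substrates was down with all libraries and up without WT replicate 2, WT replicate 3 or knockout replicate 3. The turned Krt19 passed without WT replicate 3 (adjusted p = 0.0178) and without replicate 3 of both genotypes (0.00099). Without replicate 3 the log2 fold change was 0.14 for Esrp2, 1.49 for Krt19, -0.15 for Hist1h1c, 0.082 for Atp5b, 0.12 for Psmd2 and 0.11 for Ccne1, and 0.59 for Jun. With single libraries left out, the ranges were -0.51 to -0.003 for Esrp2, -0.75 to 1.45 for Krt19, -0.31 to 0.48 for Tpx2 and -0.09 to 0.28 for Hist1h1c. They were -0.20 to 0.05 for Atp5b, -0.10 to 0.11 for Psmd2, -0.37 to 0.04 for Ccne1, -0.50 to 0.083 for Notch1 and -0.11 to 0.43 for Jun. Psmd2 was at 0.021 with upper-quartile factors and 0.077 with library size, Krt19 at 0.11 on log2(FPKM + 0.1), and Jun at -0.17 with summed replicates. Of changes of 1.5-fold, 23.9% were recovered in simulated data of this depth and spread. In that simulation 16587 of 16787 genes were unchanged, while 2705 genes were called here, so the share need not carry over. Of the 2705, 1297 changed at least 2-fold, and the others were called at smaller changes.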

Other observations

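The gene lists in this part were planned, and named genes outside the naming rule were chosen after their values were seen.

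Basement membrane and matrix genes moved in both directions. Of the collagen and matrix list 4 of 26 tested members rose and 7 fell (6 and 10 adjusted over the list alone). Col4a1, a basement membrane collagen gene, fell from 1027 ± 91.1 to 438 ± 33.7 CPM, Col4a2 from 882 ± 73.7 to 421 ± 75.0 CPM and Sparc by 0.65 on the log2 scale (SE 0.12). Fbn1 (0.78 ± 0.15) and Loxl2 (0.36 ± 0.10), outside the rule, rose beside Lum and Dcn. Without WT replicate 1, 2 members rose and 2 fell, without WT replicate 2, 2 and 4, without knockout replicate 1, 1 and 2, and without knockout replicate 2, 2 and 3. Of the matrix protease list 4 of 20 rose and 4 fell (5 and 6 adjusted over the list alone; median -0.06, mean 0.19), with Mmp12 higher (3.17 ± 0.31) and the gelatinase gene Mmp9 (-3.13 ± 0.31) and the inhibitor genes Timp2 (-0.64 ± 0.12) and Timp3 (-0.89 ± 0.13) lower. These last 3 and Adamts4 (1.03 ± 0.12) were outside the rule. Of the Wnt list 3 of 20 rose and 5 fell (3 and 6 adjusted over the list alone; fry adjusted p = 0.0342, camera adjusted p = 0.134, and adjusted p = 0.568 with an estimated correlation). Wnt5a rose from 267 ± 37.0 to 546 ± 50.7 CPM, Lef1 (1.42 ± 0.26) and Axin2 (1.40 ± 0.39, outside the rule) rose. Lgr5, the inhibitor Wif1 (-4.07 ± 0.43) and, outside the rule, Nkd1 (-1.57 ± 0.36), Sfrp1 (-1.09 ± 0.26) and Sfrp4 (-1.21 ± 0.28) fell. The Wnt members that rose were 1 without WT replicate 1 or WT replicate 2, and those that fell 3 without WT replicate 1 and 2 without knockout replicate 1 or knockout replicate 2. Camera's adjusted p was 0.0321 without WT replicate 3 and 0.0314 with the replicate block.

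Growth factor and imprinted genes held further large changes. Of the growth factor list 5 of 24 rose and 4 fell (the same adjusted over the list alone). Hgf, the hepatocyte growth factor gene, from 3.67 ± 0.38 to 14.4 ± 2.56 CPM, Igfbp4 (4.22 ± 0.43) and, outside the rule, Pdgfc (0.94 ± 0.21), Ereg (1.21 ± 0.25) and Areg (1.93 ± 0.53) rose. Fgf10, from 147 ± 44.4 to 38.8 ± 8.17 CPM, Igfbp6 (-1.51 ± 0.15) and, outside the rule, Irs1 (-1.06 ± 0.16) and Egfr (-0.98 ± 0.24) fell. The number that rose was 2 without WT replicate 1, WT replicate 2 or knockout replicate 1 and 3 without knockout replicate 2. Of 17 imprinted genes, H19 rose from 8.06 ± 3.07 to 45.4 ± 19.6 CPM and Dlk1, from 232 ± 24.6 to 38.5 ± 20.5 CPM, Ndn (-0.58 ± 0.10) and Grb10 (-0.69 ± 0.15) fell (1 and 4 adjusted over the list alone). Camera's adjusted p was 0.227, and 0.00376 without WT replicate 3, where 7 fell, while 2 rose without knockout replicate 3. Of the TGF-beta list 1 of 20 rose, Tgfb3 (0.56 ± 0.09), and Id1 (-1.22 ± 0.28), Id2 (-1.75 ± 0.21) and Ltbp2 (-1.63 ± 0.22) fell (4 and 4 adjusted over the list alone; 3 rose without WT replicate 3). With upper-quartile factors or library size only 4 rose and 3 fell, and in DESeq2 3 and 4. Of 12 hedgehog genes Foxf2 (2.92 ± 0.28) and Hhip (2.04 ± 0.47) rose (2 adjusted over the list alone; 1 without WT replicate 1, WT replicate 2 or knockout replicate 1), with a camera adjusted p of 0.0908, 0.0323 without WT replicate 2 and 0.0314 with the replicate block.

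Of 27 p53 targets 4 rose and 4 fell (the same adjusted over the list alone). Gadd45a (1.09 ± 0.11), Fas (0.87 ± 0.10), Pmaip1 (0.69 ± 0.11) and, outside the rule, Ddit4 (0.57 ± 0.10) rose. Ccng1 (-0.90 ± 0.11) and, outside the rule, Sesn1 (-0.64 ± 0.18), Ei24 (-0.42 ± 0.09) and Apaf1 (-0.37 ± 0.08) fell. 1 fell without WT replicate 1, WT replicate 2, knockout replicate 1 or knockout replicate 2. Of 22 NRF2 targets Slc7a11 and Gclm (0.45 ± 0.12) rose and Nqo1 (-1.62 ± 0.21) and Srxn1 (-0.44 ± 0.10) fell (2 and 2 adjusted over the list alone). Counts were 1 higher without WT replicate 1, WT replicate 2, knockout replicate 1 or knockout replicate 2 and 1 lower without the first 3 of these. Of 18 SCF ligase genes Usp28 (0.57 ± 0.10), Fbxo32 (1.06 ± 0.23) and Fbxl5 (0.37 ± 0.09) rose and Fbxo6 (-0.61 ± 0.12) fell (4 and 3 adjusted over the list alone). Without WT replicate 1, WT replicate 2 or knockout replicate 1, 1 rose and none fell (0 in edgeR), and with library size only 5 rose. Of 19 YAP targets F3 (0.67 ± 0.19) rose and Asap1 (-0.84 ± 0.14), Myof (-0.60 ± 0.14) and Gadd45b (-0.39 ± 0.10) fell (1 and 4 adjusted over the list alone). Without WT replicate 1, WT replicate 2, knockout replicate 1 or knockout replicate 2, 1 fell and none rose (0 in edgeR), and without WT replicate 3, 2 rose and 5 fell. Of 25 lysosome and autophagy genes 1 rose, Gla (0.69 ± 0.10), and 2 fell, among them Uvrag (-0.45 ± 0.09; the same counts adjusted over the list alone), with 5 lower without WT replicate 3 and 1 without knockout replicate 1. Of 19 unfolded protein genes Herpud1 (0.30 ± 0.08) rose, and none adjusted over the list alone (0 in edgeR, 3 at unadjusted p under 0.05), nor without any single library except knockout replicate 3, where 1 rose and 2 fell. With RLE factors 0 rose in edgeR and 1 fell, and in DESeq2 1 rose and 1 fell.

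Of 24 oxidative phosphorylation genes 0 passed in edgeR or DESeq2 (4 at unadjusted p under 0.05), with Atp5b at -0.11 ± 0.14 and Atp5a1 at 0.25 ± 0.10. Of 25 proteasome genes 0 in either (1 unadjusted), with Psmc3 at -0.17 ± 0.12 and Psmd2 at -0.02 ± 0.12. Of 10 histone genes 0 in either (1 unadjusted), with Hist1h1c at 0.13 ± 0.20 and Hist1h2bc at -0.36 ± 0.22. The other tested histone genes averaged at most 2.60 CPM in either group, and more fell below the count filter, so they show little. The same counts adjusted over the list alone were 0 for all 3 lists. Of the oxidative phosphorylation genes 3 rose with library size only and 1 without knockout replicate 3, where 1 histone gene fell. Without replicate 3 of both genotypes 5 oxidative phosphorylation and 4 proteasome genes rose and 1 histone gene fell. Of the markers of other cell types, adipocyte genes rose in 1 of 5 (Cebpa) and fell in 3, Pparg (from 8.52 ± 3.53 to 2.22 ± 0.441 CPM), Plin4 (-2.32 ± 0.43) and Fabp4 (-1.54 ± 0.35), with 1 lower without knockout replicate 2. Cartilage and bone genes rose in 3 of 9, Spp1 (from 57.8 ± 19.1 to 492 ± 25.2 CPM), Col11a2 (2.42 ± 0.18) and, outside the rule, Alpl (1.65 ± 0.38), and fell in 3, Matn3 (-2.48 ± 0.53), Col9a2 (-1.60 ± 0.34) and, outside the rule, Sox9 (-0.64 ± 0.18). 0 fell in edgeR without WT replicate 1 or knockout replicate 1 and 1 without WT replicate 2 or knockout replicate 2, and camera's adjusted p was 0.238, 0.0174 without WT replicate 3 and 0.00239 with the CPM filter. Blood markers rose in 1 of 5 (Aif1, 2.93 ± 0.38) and fell in 2 (Lyz2, -0.62 ± 0.13, and Cd68, -1.40 ± 0.34), with 0 lower in edgeR without WT replicate 1, WT replicate 2 or knockout replicate 1 and 1 without any other library, and 2 higher with upper-quartile factors or library size only. Neural markers rose in 1 of 6 (Nes, 2.54 ± 0.37) and fell in 2 (Stmn2, -3.49 ± 0.59, and Map2, -1.10 ± 0.31), with 1 lower without any single library except knockout replicate 3. Of these 4 lists the counts adjusted over the list alone were 1 and 3, 3 and 3, 2 and 2, and 1 and 2. Of 8 smooth muscle markers Rgs5 (-1.60 ± 0.39) fell (1 adjusted over the list alone), and 0 in edgeR without WT replicate 1 or any knockout replicate. Its camera adjusted p was 0.338, and 0.0257 with the replicate block. Of 3 epithelial markers 0 passed in edgeR (1 at unadjusted p under 0.05 and 1 adjusted over the list alone), and 1 in DESeq2, with Esrp2 at -0.28 ± 0.33 and Krt19 at -0.29 ± 0.76. Without WT replicate 3, Krt19 passed in the other direction (1.45, adjusted p = 0.0178). Of 5 skeletal muscle markers 0 passed in edgeR or DESeq2 (0 unadjusted), with Tnnc1 at 0.50 ± 0.28 and Tnnt1 at 0.53 ± 0.27. Of the germ and pluripotency markers Nanog alone was tested (0.34 ± 0.32), at 0.475 and 0.602 CPM, and 0 of 10 erythroid markers had enough fragments to be tested.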
